A study of Mus musculus with 19 samples.

How the data were processed

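RNA was measured in green fluorescent cells sorted from transgenic mouse embryos and newborns. The reporter is driven by a glial promoter that is active in neural crest stem cells and later in glia. Per the labels, trunk tissue was taken at E9.5, and sciatic nerve at E12, E14, E16, E18 and P0, the day of birth. Cells were sorted by flow cytometry and RNA was extracted with RNeasy kits. Target was made by 2 rounds of in vitro transcription, with biotin added in the last of them, and hybridized to Affymetrix mouse arrays. Of the E9.5 samples, replicates 2 and 3 carry no protocol text of their own, so the protocol is given for them by the other samples only.

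The deposited values are expression indices in units of intensity on a linear scale, 1 per probe set and array. Per the labels, the authors normalized the arrays to each other with the smoothing spline of dChip, computed probe sensitivities from 18 arrays and then a model-based index. The table used here holds 19 arrays, and the labels do not say which array was left out of the sensitivities. The dChip version is not given in the sources used here. The table held 12488 probe sets, with 2363 values equal to 0, a highest value of 13350.7 and 0 pairs of identical arrays. No column of values was left unused.

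Probe sets were joined to genes through the annotation of the array. Control probe sets (66) were left out. Of the rest, 10833 carried 1 gene symbol, 396 several and 1193 none. The gene identifier of 10817 of the one-symbol probe sets was found in the reference gene table, which changed 0 symbols. These probe sets stood for 8251 genes. Probe sets with several symbols or none were tested and counted but not named by gene. The gene whose promoter drives the reporter had no probe set named here and is not reported here.

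Values under the 25th percentile of all values, 68.5, were set to that floor and log2 was taken, with no further normalization. Probe sets above the floor on fewer than 3 arrays were dropped, which left 10414 in the tests. A fold whose lower stage had 1 array or more at the floor is a lower bound and is written as "at least". Folds are fitted on log2 values, so they differ from the ratio of the 2 means printed. Where that ratio was lower, the fold is given with the number of arrays at the floor. All 19 arrays went into 1 linear model with a mean per stage (limma 3.58.1, lmFit and eBayes, R 4.3.3), with 13 residual degrees of freedom. Standard errors are those of the fitted log2 change unless stated otherwise. Adjusted p-values are Benjamini-Hochberg values within a comparison, 2-sided, and the threshold was 0.05. The comparisons were each stage against the one before it and P0 against E12. Moderated F-tests covered all 6 stages and the 5 nerve stages. Nothing in the labels says whether the arrays of a stage came from separate animals or litters, so the p-values measure only the spread between these samples.

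Fixed lists of genes, 29 in number, were tested with camera at a preset correlation of 0.01, on 7414 genes with 1 probe set each, that with the highest mean. Of their 551 entries, 452 were on the array. They cover neural crest, Schwann precursor glia, immature Schwann cells, myelin, cholesterol synthesis, fatty acid and sphingolipid synthesis, the cell cycle, basal lamina and receptors, the Notch, BMP/Id and Wnt pathways, imprinted fetal growth genes, Hox genes, glycolysis, oxidative phosphorylation, ribosomal proteins, interferon and MHC genes, and dissociation stress. The others are markers of fibroblasts, endothelium, mural cells, macrophages, erythroid cells, skeletal muscle, neurons, melanocytes, somites and mesoderm, neural tube and epithelium. Adjustment ran over all 174 tests of a list in a comparison. Of the 40 lists called, 3 were also called with a correlation estimated from the data, and these are the 3 of myelin outside E18 against E16. By fry, which asks only whether a list's genes move one way on balance, 21 of the 40 were called. Counts of changed members are also given adjusted over the list alone.

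The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule took the 10 largest rises and the 10 largest falls for E12 against E9.5 and for P0 against E12, and up to 5 of each elsewhere. It required 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of both stages, which chance gives for 10% of probe sets with 3 arrays against 3. From each list described it took 2 to 4 members, by the largest change among those that passed or, where none passed, by the highest level. Names outside the rule are marked where they occur.

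Each sample carries a lot number, 1 to 4, which equals the replicate number except in E16 replicate 2, of lot 1. The lots were checked for pairing with each array's deviations from its stage mean. Across probe sets, which are not independent replicates, 39 pairs of arrays of the same lot and different stages had a mean r of 0.042, against -0.015 for 111 pairs of different lots. An r over 0.1 was found in 16 of the former and 34 of the latter. The highest r within a lot were 0.714 for E16 and P0 replicates 1, 0.524 for E16 and P0 replicates 4 and 0.469 for E16 replicate 2 with P0 replicate 1. As set before the data were examined, the lot was left out of the model and used as a block in an alternative. Changes within lots were computed for every lot that held both stages. The check leaves a lot effect in E16 and P0 open.

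The other alternatives were quantile normalization, a floor at the 10th or 40th percentile, no filter or a stricter filter, the replicate number as a block, the lot as a random block, a variance trend with robust estimation, array weights, only the 2 stages compared, and each array left out in turn. The list tests were also run on the mean of a gene's probe sets. The alternatives printed for a lost call are not always all of those that ended it. A model with the log2 GAPDH 3'/5' signal of each array as a covariate, and one without the lot-1 arrays of E16 and P0, were added after seeing the data. The number of arrays limits the precision. On simulated data of the same layout, changes of 4-fold were recovered for 86.4 to 97.0% of altered probe sets, changes of 2-fold for 41.8 to 55.2% and changes of 1.5-fold for 7.46 to 17.9%, depending on the comparison. Between 3 and 9 of the calls were false. Only probe sets above the 40th percentile of mean level were altered. The noise was independent, with the same SD at all stages and no floor. The real spread was wider at E16 and P0, so recovery there and near the floor can be lower. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.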

Results

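The 19 arrays fall into 6 stages of glial development in the mouse. At E9.5 the sorted cells were neural crest stem cells of the trunk, with 3 arrays. Sorted cells of the sciatic nerve, from Schwann cell precursors to early Schwann cells, gave 3 arrays at E12, 3 at E14, 4 at E16, 3 at E18 and 3 at P0. The median expression index per array ran from 174 to 207, and 22.6 to 27.2% of probe sets per array lay at or below the floor. Arrays of a stage had rank correlations of at least 0.949 at E12, 0.948 at E9.5, 0.937 at E18 and 0.934 at E14. The lowest was 0.895 at E16 and 0.846 at P0. P0 replicate 1 was closest to E16 replicate 1 (0.932) and P0 replicate 4 to E16 replicate 4 (0.951), while E16 replicates 3 and 4 were both closest to E18 replicate 1. The 3'/5' signal of the GAPDH control probe sets, which is higher where amplified RNA is shorter, ran from 2.33 at E9.5 replicate 2 to 9.12 at E16 replicate 2.

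E12 against E9.5 asks how cells of the early nerve differ from crest stem cells, with stage and body region changing together. Genes of Schwann cell precursors rose, 9 of 14 measured. Gfra3, a receptor subunit for the growth factor artemin, rose 10.9-fold, from 230 ± 39.5 to 2480 ± 147 (SD, n = 3 and 3; log2 change 3.44, SE 0.22). Of 19 genes of the basal lamina and its receptors 11 rose with them. Pax3 and Tfap2b, transcription factors of the early crest, fell. Pax3 fell 5.57-fold, from 1100 ± 46.3 to 197 ± 11.7 (SE of log2 0.28), and Tfap2b at least 8.09-fold from 560 ± 103 to the floor (SE 0.12). Of 28 cell cycle genes 10 fell, and of 13 glycolysis genes 7.

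In all, 1469 of 10414 probe sets changed between E9.5 and E12, 1010 up and 459 down, standing for 861 and 381 genes. Under quantile normalization 919 rose and 759 fell, and with the GAPDH signal as a covariate 1472 rose and 357 fell. Without E12 replicate 1 the count was 973. The largest rises were those of Prss12, a secreted serine protease (at least 44.5-fold, SE 0.29, adjusted p = 1.5e-09), and of Prnp, the prion protein gene (at least 35.6-fold, SE 0.16, adjusted p = 4e-12). Klf4, a transcription factor, rose at least 22.8-fold and Col3a1, a fibrillar collagen, 21.7-fold. Gria1, a glutamate receptor subunit, rose at least 22.2-fold and Ahnak, a large scaffold protein, at least 21.8-fold, since both were at the floor at E9.5. Lama4, a laminin chain, rose at least 21.5-fold, Retreg1, a receptor for degradation of endoplasmic reticulum, 19-fold, Wwtr1, a coactivator of the Hippo pathway, 18.2-fold, and Postn, a matricellular protein, 18-fold. Mtm1, a lipid phosphatase, fell 20.6-fold on 1 probe set (2 E12 arrays at the floor), and another probe set for it was not called. After Mtm1 and Tfap2b, the falls of Plcg2, a phospholipase (at least 7.17-fold), Ptn, a secreted growth factor (at least 6.49-fold), and Gbx2, a homeobox gene (at least 6.04-fold), were the next largest. Gsta4, a glutathione transferase, fell at least 5.89-fold, Ak4, an adenylate kinase, at least 5.69-fold, and Galr2, a galanin receptor, at least 5.55-fold. Ppm1g, a phosphatase, fell at least 5.89-fold (adjusted p = 0.011). Its adjusted p was 0.065 without E9.5 replicate 2, 0.058 without E12 replicate 1 and 0.056 without E12 replicate 2, and 0.00013 to 0.065 over its alternatives.

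Of 14 measured genes of Schwann precursor glia, 9 rose and 0 fell, and adjusted over the list alone 9 rose and 1 fell. Besides Gfra3 they include Ptprz1, a receptor phosphatase of glia (at least 9.56-fold, SE 0.26), Mcam, an adhesion molecule (5.93-fold, SE 0.46), and Ncam1, another one (3.70-fold, SE 0.44). The list's median log2 change was 1.19, at 1.13 and 1.14 within lots 1 and 2 (adjusted p = 1.5e-05, and adjusted p = 0.41 with an estimated correlation). Of 14 genes of immature Schwann cells, 6 rose and 0 fell, the same counts adjusted over the list alone, with a median of 0.46, or 0.39 and 0.33 within lots (adjusted p = 0.016, and adjusted p = 0.52 with an estimated correlation). Among the largest of these were Egr1 (5.11-fold), Ncam1 and Jun (3.32-fold), and Egr1 and Jun are immediate early genes that respond to many stimuli. Egr1 had an adjusted p of 0.0091, of 0.056 without E9.5 replicate 3 and of 0.055 without E12 replicate 1, and of 0.0016 to 0.056 over its alternatives. Of 19 genes of the basal lamina and its receptors, 11 rose and 0 fell, or 12 and 0 adjusted over the list alone. Lama4, Sparc, a matricellular protein (at least 14.7-fold, SE 0.46), and Lamb1, a laminin chain (5.91-fold, SE 0.25), changed most. The median was 0.99, and 0.90 and 0.58 within lots (adjusted p = 1.6e-07, and adjusted p = 0.44 with an estimated correlation).

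Cell cycle genes fell: 10 of 28 measured were lower and 0 higher at E12, or 14 and 0 adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell 4.27-fold (SE 0.48) and Mcm7, a subunit of the replicative helicase, 3.21-fold (SE 0.32). The list's median was -0.63, and -0.65 and -0.79 within lots (adjusted p = 2.6e-07, and adjusted p = 0.41 with an estimated correlation). In glycolysis 7 of 13 genes fell and 1 rose, or 9 and 1 adjusted over the list alone. Hk2, a hexokinase, fell 5.38-fold (SE 0.35) and Pfkl, a phosphofructokinase, 5.06-fold (SE 0.52), while Ldhb, a lactate dehydrogenase subunit, rose 4.60-fold (SE 0.27). The median was -1, and -1.06 and -0.87 within lots (adjusted p = 0.00028, and adjusted p = 0.44 with an estimated correlation).

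Genes that respond to cell stress and dissociation were higher at E12 too. Of 19 measured, 11 rose and 0 fell, or 13 and 0 adjusted over the list alone, with a median of 1.88, and 2.10 and 1.23 within lots 1 and 2 (adjusted p = 8e-07, and adjusted p = 0.44 with an estimated correlation). Klf4, Hspa1a, a heat shock protein (at least 14.6-fold, SE 0.93), Fos (12.6-fold, SE 0.56) and Atf3 (at least 10.5-fold, SE 0.50) changed most. Hspa1a had an adjusted p of 0.0092, of 0.063 without E12 replicate 1, and of 0.00012 to 0.063 over its alternatives. Macrophage markers rose for 6 of 13 genes and fell for 0, or 7 and 0 adjusted over the list alone. Ctss, a lysosomal protease, rose at least 10-fold to 930 ± 752 and Laptm5, a lysosomal membrane protein of blood cells, 3.17-fold. The list's median was 0.70, and 0.97 and 0.64 within lots (adjusted p = 0.0066, and adjusted p = 0.44 with an estimated correlation). It was not called with the floor at the 40th percentile (adjusted p = 0.073) or with the GAPDH signal as a covariate (adjusted p = 0.14), and ran from 0.00045 to 0.44 over its alternatives. Of 16 fibroblast markers 5 rose and 0 fell, the same adjusted over the list alone. These were Col3a1, Postn, Col1a2 (5.20-fold), Fbln2 (5.10-fold) and Col6a1 (log2 change 1.35), all genes for matrix proteins that glia can also make. The median was 0.13, and 0.20 and 0.12 within lots (adjusted p = 0.0063, and adjusted p = 0.44 with an estimated correlation), with an adjusted p of 0.22 with the GAPDH covariate and a range from 0.00015 to 0.44 over its alternatives. Of 11 erythroid markers 3 rose and 1 fell, the same adjusted over the list alone, and the embryonic globin genes Hbb-y (11.1-fold, SE 0.61) and Hba-x (at least 5.81-fold, SE 0.54) changed most. Those markers had a median of 0 and were not called as a list (adjusted p = 0.89).

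**Figure D1:**
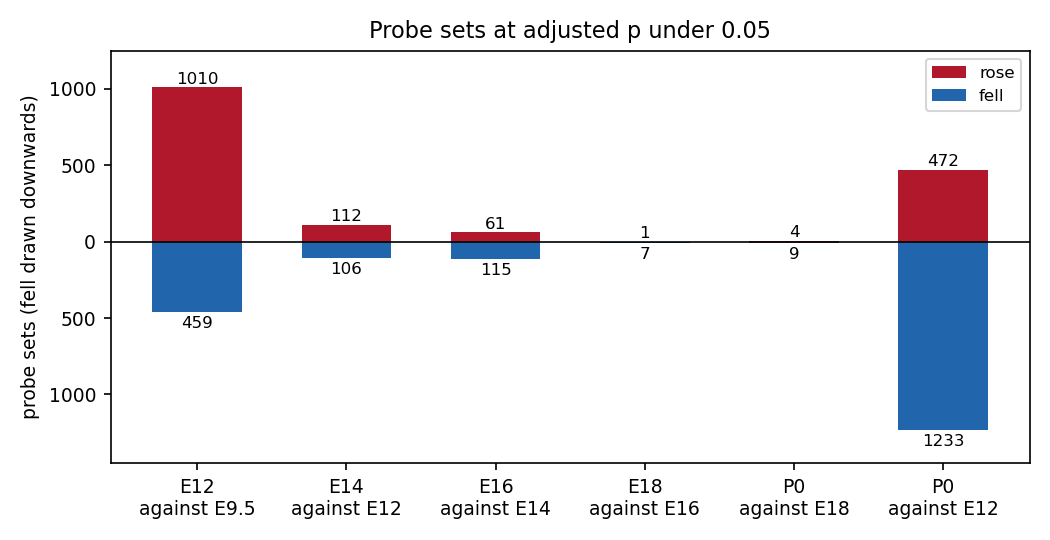
Number of probe sets with an adjusted p under 0.05 in each comparison of stages, those that rose drawn upwards and those that fell downwards from 0. The counts run from 1010 up and 459 down for E12 against E9.5 to 1 up and 7 down for E18 against E16.

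E14 against E12 is the first interval within the nerve. Myelin genes rose, 4 of 10 measured. Pmp22, a protein of peripheral myelin, rose 10.1-fold, from 232 ± 86.6 to 2250 ± 484 (SD, n = 3 and 3; log2 change 3.33, SE 0.26), and Mbp, myelin basic protein, 4.93-fold, from 190 ± 27.2 to 943 ± 175 (SE 0.25). Mal, a proteolipid of myelin membranes, rose at least 10.1-fold from the floor (SE 0.39), and Cd9, a tetraspanin of Schwann cells, 4.31-fold (SE 0.28). Of 19 basal lamina genes 4 rose with them. Col1a1, a chain of type I collagen, rose at least 48.2-fold from 67.3 ± 23.4 to 3750 ± 896 (SE 0.21).

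Between E12 and E14, 218 probe sets changed, 112 up and 106 down. With the GAPDH signal as a covariate 179 rose and 97 fell, and with array weights 406 rose and 767 fell. The GAPDH 3'/5' signal was higher on each E14 array (5.10 to 6.23) than on any E12 array (3.18 to 4.53). The count was 128 without E12 replicate 2, 135 without E14 replicate 2 and 142 without E14 replicate 3. After Col1a1 the largest rises were those of Lama2, the laminin chain of the Schwann cell basal lamina (18.6-fold, SE 0.18), Ndrg1, a gene needed to maintain peripheral myelin (14.9-fold, SE 0.27), Reln, a secreted glycoprotein (at least 14.8-fold, SE 0.28), and Mal. The largest falls were those of Mstn, a growth factor of the TGF-beta family (5.92-fold, SE 0.38), Crmp1, a regulator of axon guidance (at least 5.42-fold, SE 0.23), Scrg1 (4.12-fold, SE 0.13), Dnmt3a, a DNA methyltransferase (3.47-fold, adjusted p = 0.0024), and Nkain1 (3.36-fold, adjusted p = 0.011). Dnmt3a was not called with the floor at the 10th percentile (adjusted p = 0.13, range over its alternatives 5.9e-06 to 0.13). Nkain1 had an adjusted p of 0.073 without E12 replicate 2, 0.058 without E14 replicate 2 and 0.064 without E14 replicate 3, and of 0.00026 to 0.073 over its alternatives.

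Of 10 measured myelin genes 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. The median was 0.84, and 0.45 and 1.05 within lots 1 and 2 (adjusted p = 6e-09, and adjusted p = 0.0027 with an estimated correlation). Of 19 basal lamina genes 4 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.41, and 0.63 and 0.71 within lots (adjusted p = 3.2e-09, and adjusted p = 0.41 with an estimated correlation). They were Lama2, Itgb4, an integrin subunit (at least 3.65-fold, SE 0.43), Lamc1 (1.78-fold, SE 0.16) and Col4a1, a basal lamina collagen (1.72-fold, SE 0.18). Itgb4 and Col4a1 lost their calls without any 1 of the 6 arrays, at adjusted p-values of 0.067 to 0.1 for Itgb4 and 0.052 to 0.16 for Col4a1, and Lamc1 without E12 replicate 2 (0.056). Col4a1 lost it too with the lot block (0.06) and with the replicate block (0.054), and Itgb4 with the floor at the 40th percentile (0.21). Over their alternatives the adjusted p ran from 8.7e-05 to 0.21 for Itgb4, from 0.0015 to 0.16 for Col4a1 and from 0.00035 to 0.056 for Lamc1.

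Fibroblast markers rose for 2 of 16 genes and fell for 0, the same adjusted over the list alone, and these were the collagens Col1a1 and Col3a1 (2.10-fold, SE 0.17). The median was 0.28, and 0.35 and 0.50 within lots (adjusted p = 6.4e-05, and adjusted p = 0.36 with an estimated correlation). The stress list had 0 of 19 members called, also adjusted over the list alone, with a median of 0.72, but -0.16 within lot 1 and 1.03 within lot 2 (adjusted p = 0.00091, and adjusted p = 0.64 with an estimated correlation). Its members of highest level, Jund and Fos, had log2 changes of 0.09 (SE 0.23) and 1.00 (SE 0.56). Glycolysis had 0 of 13 genes called, also adjusted over the list alone, and a median of -0.35, with -0.21 and -0.54 within lots (adjusted p = 0.02, and adjusted p = 0.53 with an estimated correlation). Ldha and Aldoa had log2 changes of -0.50 (SE 0.17) and -0.21 (SE 0.15). The glycolysis test gave an adjusted p of 0.067 without E12 replicate 2 and 0.16 with the GAPDH covariate, from a range of 0.0055 to 0.53 over its alternatives.

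**Figure D2:**
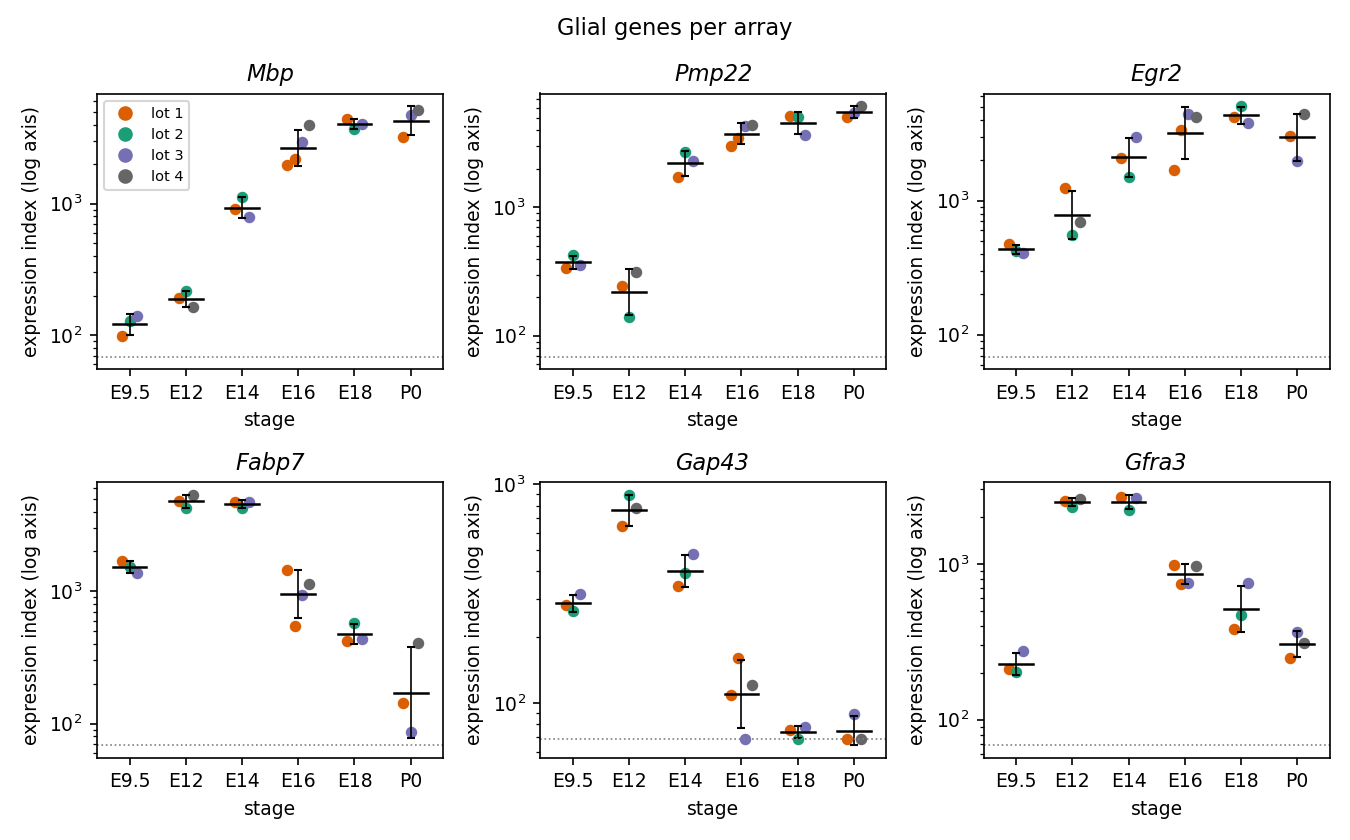
Expression index per array (log axis) for 6 glial genes across the stages, coloured by lot, with the geometric mean and SD as bars and the floor as a dotted line. The arithmetic mean of Mbp was 190 at E12 and 4370 at P0, and that of Fabp7 4820 and 211.

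E16 against E14 is the next interval of the nerve. Genes of Schwann cell precursors fell, 4 of 14 measured. Fabp7, a fatty acid binding protein of immature glia, fell 4.75-fold, from 4570 ± 283 to 1020 ± 382 (SD, n = 3 and 4; log2 change -2.25, SE 0.39). Gap43, a growth-associated protein, fell 3.67-fold, from 407 ± 69.9 to 114 ± 39.1 (SE 0.22, 1 E16 array at the floor), and Gfra3 2.93-fold, from 2510 ± 256 to 863 ± 128 (SE 0.21). Mbp rose a further 2.84-fold, to 2750 ± 894 (SE 0.23). The list of cholesterol synthesis was higher at E16 (adjusted p = 3.6e-07, and adjusted p = 0.41 with an estimated correlation).

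Between E14 and E16, 176 probe sets changed, 61 up and 115 down. Without the lot-1 arrays of E16 and P0 more rose than fell, 120 against 84, and under quantile normalization 100 rose and 130 fell. Without E14 replicate 1 the count was 114, without E14 replicate 3 it was 107, and with the GAPDH covariate it was 272. The largest rises were those of Anxa1, an annexin (at least 11.1-fold, SE 0.40), Col15a1, a collagen of basement membrane zones (9.03-fold, SE 0.39), Fgl2, a secreted fibrinogen-like protein (6.76-fold, SE 0.31), Srgap2, a regulator of cell shape (at least 6.08-fold, SE 0.25), and Gatm, an enzyme of creatine synthesis (6.07-fold, SE 0.36). The largest falls were those of Dkk2, a Wnt modulator (at least 8.92-fold, SE 0.13), Cadps, a factor for vesicle release (at least 8.83-fold, SE 0.14), Dlx1, a homeobox gene (8.61-fold, SE 0.74, 1 E16 array at the floor), Hbb-y (8.55-fold, SE 0.57) and Vcan, the matrix proteoglycan versican (8.31-fold, SE 0.34). Dlx1 had an adjusted p of 0.042. It lost its call without any 1 of E14 replicates 1, 2 and 3 and E16 replicates 1, 2 and 4 (0.063 to 0.16) and with the lot block (0.058), from a range of 0.0038 to 0.3 over its alternatives.

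Of 14 genes of Schwann precursor glia 4 fell and 0 rose, or 4 and 1 adjusted over the list alone, with a median of -0.44, and -0.45 and -0.16 within lots 1 and 3 (adjusted p = 0.0048, and adjusted p = 0.52 with an estimated correlation). Without the lot-1 arrays of E16 and P0 its adjusted p was 0.18, from a range of 0.00067 to 0.52. Of 10 myelin genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone, with a median of 0.44, and 0.33 and 0.44 within lots (adjusted p = 2.3e-05, and adjusted p = 0.016 with an estimated correlation). They were Mbp and Mal (3.40-fold, SE 0.36), and Mal had an adjusted p of 0.12 without E14 replicate 1 and 0.06 without E14 replicate 3, from 0.00065 to 0.12 over its alternatives. Cholesterol synthesis was higher in all 16 measured genes by the fitted change. Of these 1 rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.46, and 0.27 and 0.81 within lots 1 and 3 (adjusted p = 3.6e-07, and adjusted p = 0.41 with an estimated correlation). That gene was Fdps, farnesyl diphosphate synthase (3.00-fold, SE 0.32), with an adjusted p of 0.012, of 0.051 without E14 replicate 2 and of 0.067 without E14 replicate 3, from 0.00056 to 0.067. The list's score, a mean log2 deviation, was 0.03 and 0.00 on E16 replicates 1 and 2 and 0.71 and 0.58 on replicates 3 and 4, which stand apart from them. Basal lamina genes rose for 2 of 19 and fell for 0, the same adjusted over the list alone, with a median of 0.37, and 0.28 and 0.57 within lots (adjusted p = 7.6e-05, and adjusted p = 0.52 with an estimated correlation). Its score split in the same way, at 0.317 and 0.335 on E16 replicates 1 and 2, within the E14 range of 0.056 to 0.364, and 0.819 and 1.007 on replicates 3 and 4. Those called were Lama2 (2.83-fold, SE 0.17) and Col5a1 (2.20-fold, SE 0.27). Col5a1 lost its call with the lot block (0.054) and without any 1 of E14 replicates 1 and 2 and the 4 E16 arrays (0.051 to 0.26), from 0.0081 to 0.26 over its alternatives.

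The cell cycle list had 0 of 28 genes called, also adjusted over the list alone, with a median of 0.16, but -0.02 within lot 1 and 0.47 within lot 3 (adjusted p = 0.02, and adjusted p = 0.71 with an estimated correlation). Pcna and Cdc20, its members of highest level, had log2 changes of 0.15 (SE 0.17) and 0.07 (SE 0.17). This list lost its call without E14 replicate 1 (0.058), E14 replicate 2 (0.11), E16 replicate 3 (0.13) or E16 replicate 4 (0.063) and with the replicate block (0.06), from 0.0034 to 0.71. Glycolysis rose for 1 of 13 genes and fell for 0, or 5 and 2 adjusted over the list alone, with a median of 0.24, and 0.15 and 0.41 within lots (adjusted p = 0.0067, and adjusted p = 0.52 with an estimated correlation). That gene was Ldha, a lactate dehydrogenase subunit (1.63-fold, SE 0.16), whose call ended without any 1 of the arrays except E16 replicate 1 (0.064 to 0.13), from 0.0021 to 0.13 over its alternatives. The glycolysis score was -0.397 and -0.343 on E16 replicates 1 and 2, beside -0.385 to -0.305 at E14. On E16 replicates 3 and 4 it was -0.087 and 0.086. Fibroblast markers rose for 3 of 16 genes and fell for 0, the same adjusted over the list alone, with a median of 0.23, and 0.45 and 0.17 within lots (adjusted p = 0.00017, and adjusted p = 0.41 with an estimated correlation). They were Lox, an enzyme of collagen cross-linking (at least 3.28-fold, SE 0.29), Ogn, a matrix proteoglycan (at least 3.10-fold, SE 0.39), and Col1a1 (1.81-fold, SE 0.20). Without the lot-1 arrays of E16 and P0 the list had an adjusted p of 0.16, from 1.9e-05 to 0.41. Ogn lost its call with the lot block (0.099) and without any 1 of the E14 arrays and E16 replicates 1 and 2 (0.12 to 0.16), from 0.0023 to 0.28. Col1a1 lost it without E14 replicate 1 (0.23), E14 replicate 3 (0.054), E16 replicate 2 (0.096) or E16 replicate 3 (0.079), from 0.0026 to 0.23. The score of the fibroblast list was 1.32 on E16 replicate 2 and 0.46, 0.44 and 0.56 on replicates 1, 3 and 4. Macrophage markers fell for 1 of 13 genes and rose for 0, or 3 and 0 adjusted over the list alone, with a median of -0.32, and -0.46 and -0.26 within lots (adjusted p = 0.0079, and adjusted p = 0.44 with an estimated correlation). The gene was Ctss (at least 4.57-fold, SE 0.51), which lost its call without any 1 of E14 replicates 1 and 2 and E16 replicates 1, 3 and 4 (0.067 to 0.24), from 0.0071 to 0.24. The macrophage list had an adjusted p of 0.06 without E14 replicate 1, 0.059 without E16 replicate 4 and 0.062 with the replicate block, from 0.00091 to 0.44.

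**Figure D3:**
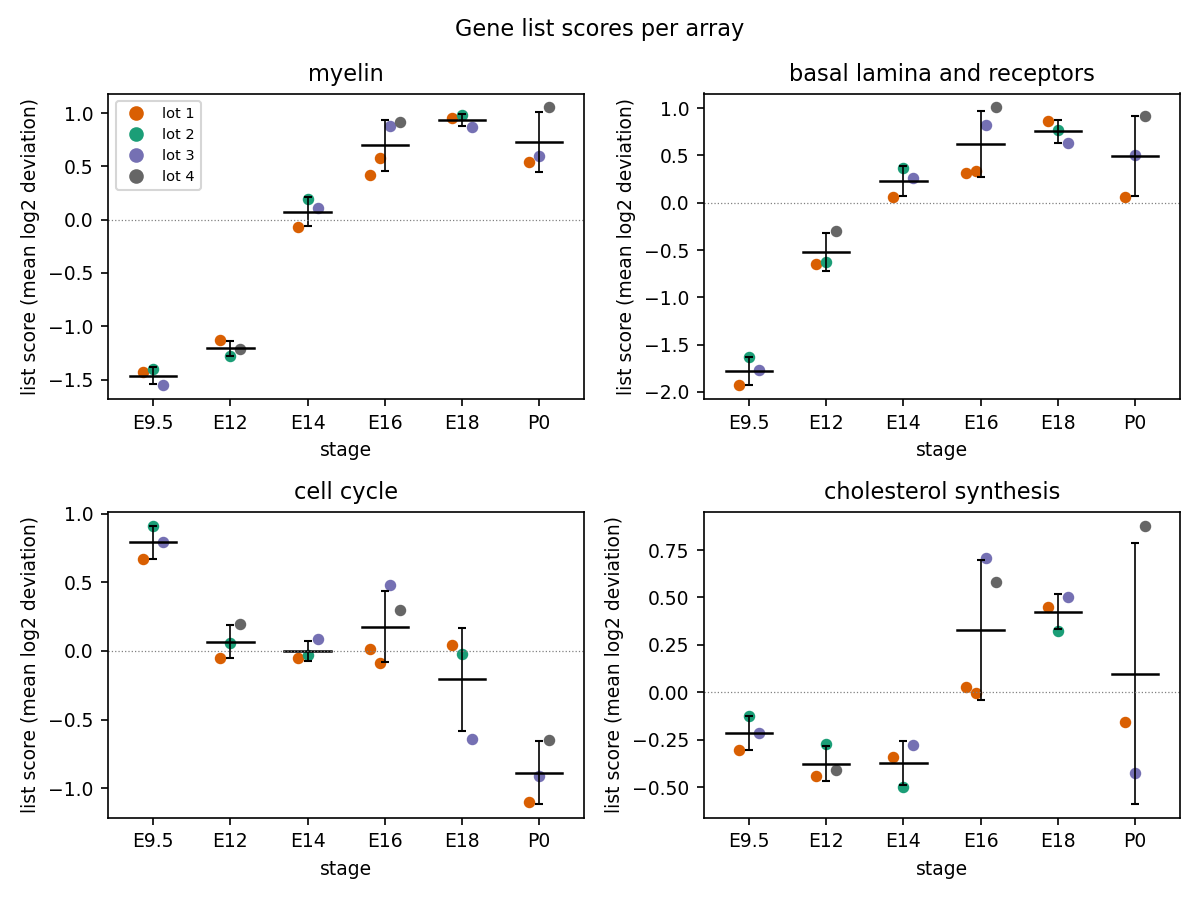
Score of 4 gene lists on each array (mean log2 deviation of the list's genes from their mean over all arrays), coloured by lot, with the mean and SD of each stage. On the cholesterol synthesis panel E16 replicates 1 and 2 lie at 0.03 and 0.00, and replicates 3 and 4 at 0.71 and 0.58.

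E18 against E16 gave few calls, which does not show that few genes changed. Vcan, the matrix proteoglycan, fell at least 6.02-fold from 472 ± 245 to the floor (SD, n = 4 and 3; log2 change -2.59, SE 0.34, adjusted p = 0.0022). Sncg, gamma-synuclein, fell 2.73-fold, from 606 ± 32.2 to 223 ± 24 (SE 0.17, adjusted p = 0.0012), and its other probe set fell too. Padi2, an enzyme that citrullinates myelin basic protein and other proteins, rose 3.06-fold, from 133 ± 24.8 to 420 ± 153 (SE 0.28, adjusted p = 0.038). Ccdc80, a secreted matrix protein, fell 2.05-fold (SE 0.17, adjusted p = 0.038) and Ipo5, a nuclear import factor, 1.85-fold (SE 0.16, adjusted p = 0.042).

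In all, 1 probe set rose and 7 fell between E16 and E18, while 840 of 10414 had an unadjusted p under 0.05 in the linear model. With array weights 1153 were called. E16 replicates 1 and 2 stood apart from replicates 3 and 4, and such a spread can hide changes. Under quantile normalization 4 rose and 6 fell, and with the lot block 5 changed. The count was 4 without E16 replicate 1, 5 without E16 replicate 2 and 4 without E18 replicate 1, 2 or 3. Padi2 lost its call without any 1 of E16 replicates 1, 2 and 3 and the 3 E18 arrays (0.089 to 0.21) and with the lot block (0.094), from 0.0017 to 0.21 over its alternatives. Ccdc80 lost it without any 1 of the arrays except E16 replicate 2 (0.062 to 0.2) and with the lot block (0.09), from 0.00075 to 0.48. Ipo5 lost it without any 1 of the arrays except E16 replicate 3 (0.096 to 0.28) and with the lot block (0.17), from 0.00024 to 0.28. Vcan was not called with the floor at the 40th percentile (adjusted p = 0.12), from 1.6e-06 to 0.12.

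Lists called between E16 and E18 had 0 members called, also adjusted over the list alone, so their tests rest on small joint shifts. Of 28 cell cycle genes 1 had a positive change, with a median of -0.35, but 0.06 within lot 1 and -1.17 within lot 3 (adjusted p = 1.3e-05, and adjusted p = 0.44 with an estimated correlation). Pcna and Cdc20 both had a log2 change of -0.06 (SE 0.17). Without E18 replicate 3 the cell cycle list had an adjusted p of 0.079, from 9.9e-08 to 0.44. Of 10 myelin genes 8 were higher, with a median of 0.25, and 0.51 and 0.11 within lots 1 and 3 (adjusted p = 0.028, and adjusted p = 0.36 with an estimated correlation). Egr2, a transcription factor that drives myelination, had a log2 change of 0.44 (SE 0.35) and Pmp22 one of 0.28 (SE 0.24). The myelin list lost its call with the lot block (0.066), the replicate block (0.056) or quantile normalization (0.057). It lost it too without E16 replicate 3 (0.068), E16 replicate 4 (0.05) or E18 replicate 2 (0.11). The floor at the 10th percentile gave 0.081 and omission of the lot-1 arrays of E16 and P0 gave 0.1. Fry gave 0.094 and the mean of a gene's probe sets 0.069, from a range of 0.02 to 0.36. Of 13 glycolysis genes 11 were higher, with a median of 0.30, and 0.29 and 0.19 within lots (adjusted p = 0.0046, and adjusted p = 0.49 with an estimated correlation). Ldha and Aldoa had log2 changes of 0.24 (SE 0.16) and 0.18 (SE 0.14). Of 15 ribosomal protein genes 13 were higher, with a median of 0.15, and 0.23 and 0.16 within lots (adjusted p = 0.0063, and adjusted p = 0.52 with an estimated correlation). Rpl41 and Rps24 had log2 changes of 0.10 (SE 0.16) and 0.15 (SE 0.12). The ribosomal list lost its call without E16 replicate 3 (0.14), from 0.00022 to 0.52. Of 19 stress genes 17 were higher, with a median of 0.41, and 0.81 and 0.13 within lots (adjusted p = 0.0013, and adjusted p = 0.65 with an estimated correlation). Jund and Fos had log2 changes of -0.08 (SE 0.21) and 0.01 (SE 0.53).

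P0 against E18 spans birth. Hbb-b2, an adult beta globin, fell at least 18.9-fold, from 1690 ± 540 to 68.6 ± 59.9 (SD, n = 3 and 3; log2 change -4.24, SE 0.52, adjusted p = 0.0023). Its index ran from 593 to 2500 on the E16 arrays, and erythroid cells in the sorts were not tested as its source. Pdk1, a kinase that inhibits the pyruvate dehydrogenase complex, fell 3.85-fold, from 539 ± 202 to 134 ± 9.67 (SE 0.22, adjusted p = 0.0017). P4ha1, a collagen prolyl hydroxylase, fell 3.77-fold (SE 0.35, adjusted p = 0.04), Anln, a protein of dividing cells, 3.34-fold (SE 0.32, adjusted p = 0.04), and Pgam1, a glycolytic enzyme, 2.62-fold (SE 0.23, adjusted p = 0.027). Pdk1, P4ha1 and Pgam1 are known targets of the hypoxia response. Aldh1a7, an aldehyde dehydrogenase, rose at least 2.35-fold (SE 0.22, adjusted p = 0.04) and Cirbp, an RNA-binding protein induced by cold, 1.79-fold (SE 0.13, adjusted p = 0.027).

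Between E18 and P0, 4 probe sets rose and 9 fell. The other rises, named after their values were seen because they are few, were those of Slc6a6, a taurine transporter (log2 change 1.34, SE 0.22), and Efhd2 (log2 change 0.88, SE 0.15), and the arrays of both stages overlap for these. The count was 4 without E18 replicate 1, 2 without E18 replicate 2, 58 without E18 replicate 3, 4 without P0 replicate 1, 6 without P0 replicate 3 and 715 without P0 replicate 4. It was 56 under quantile normalization and 40 with the replicate block. Hbb-b2 and Pdk1 passed the threshold under each alternative that was run for single genes (highest adjusted p 0.03 and 0.023). With only both stages in the model, run for counts alone, 0 probe sets were called, so neither gene passed there. Aldh1a7, Cirbp, P4ha1, Anln and Pgam1 each lost the call without 1 array or more. The highest of these adjusted p-values came without E18 replicate 2, at 0.18 for Aldh1a7, 0.17 for Cirbp, 0.17 for P4ha1, 0.22 for Anln and 0.17 for Pgam1. The lowest adjusted p over their alternatives was 0.0037, 0.0032, 0.0016, 0.0016 and 5.7e-05, in the same order, and Aldh1a7 reached 0.38 with the floor at the 40th percentile. Without E18 replicate 1 the values for Aldh1a7, Anln, P4ha1 and Pgam1 were 0.13, 0.2, 0.16 and 0.062. Without P0 replicate 1 those for Aldh1a7, Cirbp, Anln, P4ha1 and Pgam1 were 0.057, 0.074, 0.12, 0.16 and 0.094. Without P0 replicate 3 those for Aldh1a7, Anln, P4ha1 and Pgam1 were 0.088, 0.067, 0.13 and 0.099. With the lot block Aldh1a7 and Anln both had 0.055.

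Cell cycle genes were lower at P0 than at E18, though only Ccnb2, a mitotic cyclin, passed by itself (1.99-fold, SE 0.17, adjusted p = 0.027). Of 28 measured 1 fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of -0.83, and -1.36 and -0.14 within lots 1 and 3 (adjusted p = 2.7e-10, and adjusted p = 0.36 with an estimated correlation). Ccnb2 had an adjusted p of 0.15 without E18 replicate 1, 0.17 without E18 replicate 2, 0.094 without P0 replicate 1, 0.059 without P0 replicate 3 and 0.054 with the lot block, from 0.0016 to 0.17. In glycolysis 1 of 13 genes, Pgam1, fell and 0 rose, or 7 and 0 adjusted over the list alone, with a median of -0.89, and -1.29 and -0.66 within lots (adjusted p = 1.7e-05, and adjusted p = 0.41 with an estimated correlation). Precursor glia genes had 0 of 14 called, or 4 lower and 0 higher adjusted over the list alone, with a median of -0.44, and -0.79 and -0.20 within lots (adjusted p = 0.012, and adjusted p = 0.53 with an estimated correlation). Erbb3, the receptor for axonal neuregulin, had a log2 change of -0.43 (SE 0.29) and Sox2, a transcription factor of immature glia, one of -0.45 (SE 0.27). That list lost its call without P0 replicate 1 (0.24) and with the GAPDH covariate (0.17), from 0.0023 to 0.53. Imprinted fetal growth genes had 0 of 13 called, also adjusted over the list alone, with a median of -0.55, but 0.00 within lot 3 and -0.55 within lot 1 (adjusted p = 0.0073, and adjusted p = 0.44 with an estimated correlation). Gnas and Cdkn1c had log2 changes of 0.02 (SE 0.15) and 0.04 (SE 0.30). Stress genes had 0 of 19 called, or 1 lower and 0 higher adjusted over the list alone, with a median of -0.62, and -0.67 and -0.91 within lots (adjusted p = 0.00015, and adjusted p = 0.53 with an estimated correlation). Jund and Fos had log2 changes of 0.11 (SE 0.23) and -0.25 (SE 0.56). P0 replicate 4, outside the lots compared, stood apart from P0 replicates 1 and 3. Scores on replicates 1, 3 and 4 were -0.963, -0.528 and 0.072 for glycolysis (0.13 to 0.267 at E18), 0.04, -0.364 and 0.966 for stress (0.658 to 1.179 at E18), and -0.691, -0.303 and 0.177 for precursor glia (0.032 to 0.233 at E18). For imprinted genes they were -0.826, -0.775 and -0.245 (-0.379 to 0.005 at E18). Cell cycle scores were -1.103, -0.909 and -0.649 on P0 replicates 1, 3 and 4. On E18 replicates 1, 2 and 3 they were 0.04, -0.024 and -0.64, so E18 replicate 3 lay near P0 replicate 4. The 3'/5' signal of GAPDH was 7.69, 6.80 and 4.69 on P0 replicates 1, 3 and 4.

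P0 against E12 compares the last nerve stage with the first. Myelin genes rose, 5 of 10 measured, with Mbp up 22.7-fold to 4370 ± 1030 from 190 ± 27.2 (SD, n = 3 and 3; log2 change 4.5, SE 0.25, adjusted p = 2.7e-09) and Pmp22 25.2-fold to 5580 ± 562 from 232 ± 86.6 (SE 0.26). Col1a1 rose at least 79.9-fold to 6210 ± 1510 (SE 0.21) and Lama2 57.4-fold to 6030 ± 876 (SE 0.18). Fabp7 fell 28.1-fold to 211 ± 170 from 4820 ± 553 (SE 0.41), and the homeobox genes Dlx2 at least 19.7-fold (SE 0.40) and Dlx1 at least 26-fold (SE 0.79). Vcan fell at least 73.5-fold from 5070 ± 719 to the floor (SE 0.36).

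Between E12 and P0, 1705 probe sets changed, 472 up and 1233 down, standing for 394 and 1043 genes. Under quantile normalization 760 rose and 1103 fell, and with the GAPDH signal as a covariate 554 rose and 655 fell. That 3'/5' signal was higher on each P0 array (4.69 to 7.69) than on any E12 array (3.18 to 4.53). Without E12 replicate 2 the count was 1063 and without P0 replicate 4 it was 2794. Other large rises were those of Mal (at least 25.7-fold), Gatm (at least 22.8-fold), Itih5, a protein that binds hyaluronan-rich matrix (19.9-fold), S100a6, a calcium-binding protein (at least 19.5-fold), Reln (at least 18.6-fold) and Ndrg1 (17.8-fold). Other large falls were those of Hbb-y (19.2-fold), Lsr, a component of tricellular junctions (at least 15.3-fold), Id3, an inhibitor of helix-loop-helix factors (14.5-fold), Igf2bp1, a fetal RNA-binding protein (14-fold), Cadps (at least 13.5-fold) and Igf2, a fetal growth factor (13.2-fold, adjusted p = 0.0023).

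Of 10 myelin genes 5 rose and 0 fell, the same adjusted over the list alone, with a median of 1.19, and 0.90 and 1.81 within lots 1 and 4 (adjusted p = 4.6e-07, and adjusted p = 0.0053 with an estimated correlation). Of 19 basal lamina genes 8 rose and 2 fell, or 12 and 2 adjusted over the list alone, with a median of 0.86, and 0.48 and 1.05 within lots (adjusted p = 4.8e-07, and adjusted p = 0.44 with an estimated correlation). Besides Lama2, Itgb4 rose at least 10.3-fold (SE 0.43), while Agrn, the heparan sulfate proteoglycan agrin, fell 3.59-fold (SE 0.35). Of 14 genes of immature Schwann cells 4 rose and 1 fell, the same adjusted over the list alone, with a median of 0.42, and 0.04 and 0.77 within lots (adjusted p = 0.014, and adjusted p = 0.52 with an estimated correlation). Pou3f1, a transcription factor of promyelinating cells, rose at least 10.3-fold (SE 0.60) and Cd9 5.86-fold (SE 0.28), while Igf1r, a growth factor receptor, fell 3.03-fold (SE 0.28). Without P0 replicate 4 this list had an adjusted p of 0.081, from 0.001 to 0.52. Cholesterol synthesis rose for 2 of 16 genes and fell for 0, the same adjusted over the list alone, with a median of 0.36, and 0.33 and 1.25 within lots (adjusted p = 0.011, and adjusted p = 0.68 with an estimated correlation). It had an adjusted p of 0.25 without P0 replicate 4, from 0.00015 to 0.68, and its score was -0.16, -0.42 and 0.88 on P0 replicates 1, 3 and 4. The genes were Msmo1, a sterol oxidase (2.94-fold, SE 0.44), and Fdps (2.36-fold, SE 0.34). Msmo1 lost its call without E12 replicate 2 (0.076), E12 replicate 4 (0.065), P0 replicate 1 (0.055) or P0 replicate 4 (0.072), from 0.0027 to 0.076. Fdps lost it without E12 replicate 1 (0.083), E12 replicate 4 (0.051) or P0 replicate 4 (0.059), from 0.00084 to 0.083.

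Cell cycle genes fell from E12 to P0 in 14 of 28 cases, with 0 rising, or 16 and 0 adjusted over the list alone. Cdc6, a replication licensing factor, fell at least 4.51-fold (SE 0.33), Mcm3, a helicase subunit, 3.91-fold (SE 0.29), and Cks2, a cyclin kinase subunit, 3.38-fold (SE 0.32). The median was -1.10, and -1.14 and -0.89 within lots (adjusted p = 1.2e-05, and adjusted p = 0.44 with an estimated correlation). Imprinted fetal growth genes fell for 5 of 13 and rose for 0, or 6 and 0 adjusted over the list alone. Besides Igf2 they include Mest (12.1-fold, SE 0.37) and Igf2r, the receptor that clears Igf2 (4.17-fold, SE 0.36). The list's median was -0.34, but -0.66 within lot 1 and 0.00 within lot 4 (adjusted p = 0.024, adjusted p = 0.066 with the lot block, and adjusted p = 0.52 with an estimated correlation, the range being 0.0025 to 0.52). Interferon and MHC genes rose for 4 of 14 and fell for 0, or 5 and 0 adjusted over the list alone, with a median of 0.47, and 0.31 and 0.88 within lots (adjusted p = 0.001, and adjusted p = 0.36 with an estimated correlation). Tap1, a peptide transporter, rose at least 2.75-fold (SE 0.22) and Irf1, a transcription factor, 3.31-fold (SE 0.52). Irf1 lost its call without E12 replicate 2 (0.11), E12 replicate 4 (0.085), P0 replicate 1 (0.097) or P0 replicate 4 (0.075), from 0.012 to 0.11, and Tap1 with the floor at the 40th percentile (0.057), from 4.3e-06 to 0.057.

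Fibroblast markers rose for 4 of 16 genes and fell for 0, or 5 and 1 adjusted over the list alone, with a median of 0.35, and 0.39 and 0.38 within lots (adjusted p = 0.0022, and adjusted p = 0.44 with an estimated correlation). They were Col1a1, Lox (at least 4.16-fold, SE 0.31), Col3a1 (2.76-fold, SE 0.17) and Col1a2 (2.34-fold, SE 0.27), all of them collagens or a collagen cross-linking enzyme. With the GAPDH covariate the list had an adjusted p of 0.071, from 0.00074 to 0.44. Macrophage markers fell for 4 of 13 genes and rose for 0, or 5 and 0 adjusted over the list alone, with a median of -0.54, and -0.79 and -0.34 within lots (adjusted p = 0.038, and adjusted p = 0.52 with an estimated correlation). Ctss fell at least 10-fold (SE 0.54), C1qc, a complement component, at least 3.16-fold (SE 0.26), and Laptm5 3.13-fold (SE 0.28). The macrophage list lost its call without E12 replicate 1 (0.094), P0 replicate 4 (0.34) or the lot-1 arrays of E16 and P0 (0.056). It lost it too with the floor at the 40th percentile (0.21) and with array weights (0.31), from 0.0011 to 0.52.

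**Figure D4:**
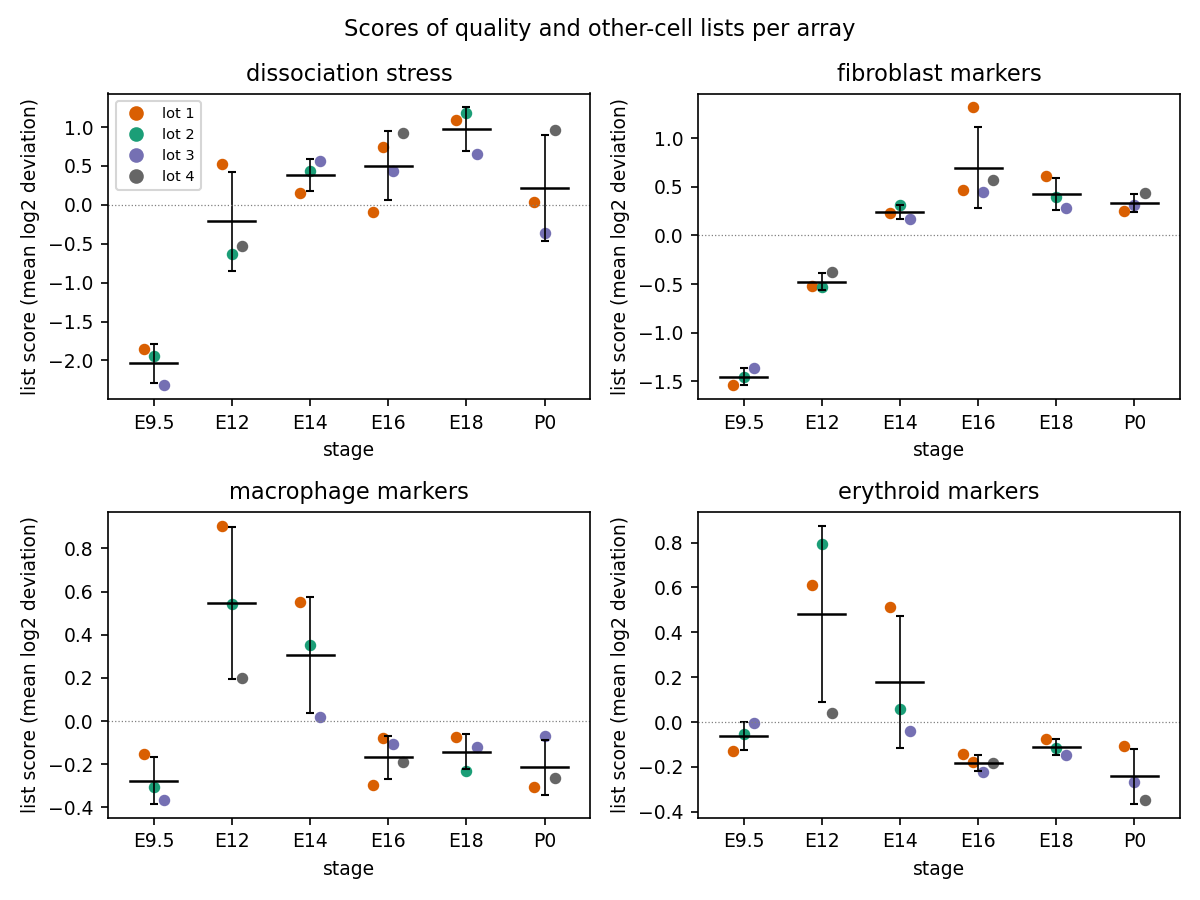
Score of the stress list and of marker lists of fibroblasts, macrophages and erythroid cells on each array (mean log2 deviation), coloured by lot, with the mean and SD of each stage. The fibroblast score of E16 replicate 2, at 1.32, lies above those of the other E16 arrays, at 0.46, 0.44 and 0.56.

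Across all 6 stages 3018 probe sets changed, and across the 5 nerve stages 1364. The latter count was 867 without E12 replicate 2 and 2357 without P0 replicate 4. Of the 29 lists 16 were called in no comparison. The lowest adjusted p of each was 0.075 for endothelial markers, 0.1 for neuron markers, 0.11 for the Wnt pathway, 0.14 for melanocyte markers, and 0.15 for neural crest, for fatty acid and sphingolipid synthesis and for oxidative phosphorylation. It was 0.17 for Hox genes, 0.28 for the BMP/Id pathway and for neural tube markers, 0.29 for epithelial markers, 0.32 for the Notch pathway, 0.53 for skeletal muscle markers, 0.58 for somite and mesoderm markers, 0.65 for erythroid markers and 0.78 for mural cell markers. Of the 40 lists called, 35 kept the direction of the pooled change within each lot that held both stages. With array weights the counts of changed probe sets were higher throughout, from 865 for P0 against E18 to 6462 for the 6 stages.

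**Figure D5:**
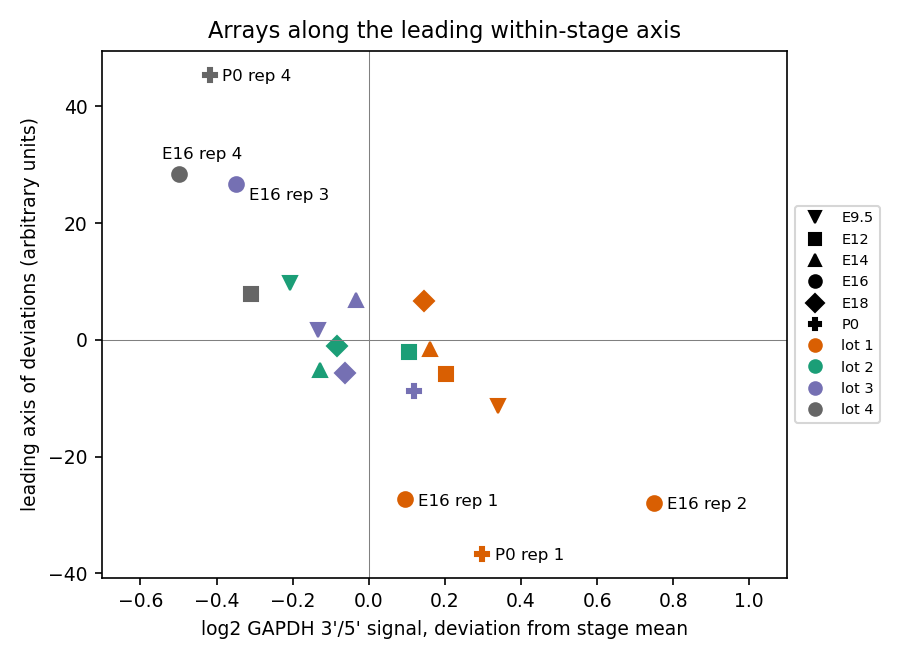
Position of each array on the leading axis of deviations from the stage means (arbitrary units) against the log2 GAPDH 3'/5' signal as a deviation from the stage mean, with stages as symbols and lots as colours. E16 replicates 1 and 2 and P0 replicate 1 lie from -27.3 to -36.6, and E16 replicates 3 and 4 and P0 replicate 4 from 26.8 to 45.4.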

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

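The tests of handling, macrophages, amplification, lot, embryo age and fibroblasts below were chosen only after the results they address were seen. Among 95 groups of 4 E16 arrays tested for a value far from the others, 29 list scores, 61 named genes and 5 array measures, 2 stood out, both on E16 replicate 2, and chance gives about 1 in 20. The fibroblast list had a score of 1.32 on E16 replicate 2 and of 0.46, 0.44 and 0.56 on replicates 1, 3 and 4. Tfap2b had an expression index of 3.32 on E16 replicate 2 and of 0 on the others, all below the floor.

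The stress list, of immediate early and heat shock genes, was higher at E12 than at E9.5, with 11 of 19 members up. Macrophages in the nerve sorts stay open for E12, where macrophage scores of 0.904, 0.54 and 0.2 on replicates 1, 2 and 4 stood beside stress scores of 0.525, -0.629 and -0.524. At P0 the list's median lay 2.49 above its E9.5 level, higher for 17 of 19 genes. Its SE of 0.49 came from a bootstrap over genes, which vary together, and leaves out the spread between arrays. Stress scores were -1.848, -1.945 and -2.321 on the E9.5 arrays and 0.04, -0.364 and 0.966 on the P0 arrays. The median macrophage marker was back at a difference of 0.00, which argues against macrophages as the source of the P0 level. Ctss and C1qc were at the floor on all arrays of both stages, so a small difference in macrophages would not show in them. Handling that differed from array to array stays open. Members of the stress list varied together among arrays of the same stage, with a mean pairwise correlation of 0.45. Matched random lists had a median of 0.11 and a 95th percentile of 0.26, which puts the list at percentile 100 of 10000. The random lists were matched on level only, so any cause that moves these genes together would give a high percentile. Covariation within stages does not bear on the difference between E9.5 and E12. A difference in biology between trunk crest and nerve stays open and untested, as does handling that differed between tissues.

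Arrays of E16 and of P0 stand apart from others of their stage along an axis that holds 37% of the variance within stages. A lot effect of equal size in all stages is argued against. Lot-1 arrays of the other 4 stages lay at a mean of -3.0 (SE 3.8, n = 4) and those of E16 and P0 at -30.6 (SE 3.0, n = 3). The latter were picked as far out, on an axis that the stages of widest spread shape most. A smaller common effect therefore stays open. A lot effect in E16 and P0 alone stays open, untested. Deviations of their arrays of one lot had r of 0.714, 0.469 and 0.524 in lots 1, 1 and 4 and -0.134 in lot 3. Of their pairs of different lots, E16 replicate 3 with P0 replicate 4 had r of 0.468, and the others -0.674 to 0.247. E16 embryos of different ages stay open: the split of the E16 arrays had r = 0.18 across probe sets with the change from E14 to E18 (jackknife SE 0.12), myelin scores ran with age at 0.418 and 0.574 on replicates 1 and 2 and 0.878 and 0.919 on replicates 3 and 4 (-0.071 to 0.19 at E14, 0.871 to 0.978 at E18), and precursor scores ran against it at -0.045 and -0.185, then 0.231 and 0.483 (0.506 to 0.824 at E14, 0.032 to 0.233 at E18). Uneven RNA amplification is a candidate explanation: over 19 arrays the axis had r = -0.81 with the log2 GAPDH 3'/5' signal (permutation p = 0.002, rho -0.83 with permutation p = 0.0029) and r = -0.91 with that of actin (permutation p = 0.00056, rho -0.90 with permutation p = 0.001), and for these 2 relations the adjusted values were 0.002 and 0.0011 for r and 0.0029 and 0.002 for rho. Without the 2 arrays farthest from the median r was -0.78 and -0.87, and within lot 1, the only lot of at least 6 arrays (n = 7), r was -0.43 for GAPDH (exact p = 0.36, rho -0.50 with exact p = 0.27), which did not pass, and -0.84 for actin (exact p = 0.012, rho -0.79 with exact p = 0.048).

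Col1a1 was higher at P0 than at E12 by a log2 change of at least 6.32 (SE 0.21). Fibroblasts in the nerve sorts are argued against as the source of that rise, since the other 13 fibroblast markers outside the fibrillar collagens had a median change of 0.06 (quartiles -0.08 and 0.42), and Dcn, among the most abundant fibroblast transcripts, had an index of 143 to 188 at P0. The highest change of the 13 was that of Lox, at least 2.06. Expression of Col1a1 by the sorted glia stays open as a hypothesis, untested. Whether fibroblasts passed the sort in E16 replicate 2 stays open: 10 of the 13 markers were highest on that array, which its high list score largely fixes. Dcn was at 3395 there, against 357, 123 and 236 on the other E16 arrays. It is named in this paragraph outside the rule, after its values were seen.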

How the results depend on the processing

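Of 221 calls of named genes and 40 of lists, 0 reversed direction under the alternatives run for them, which leave out the other filters and the fits with only both stages, run for counts alone. The covariate for the GAPDH 3'/5' signal and the omission of the lot-1 arrays of E16 and P0 were chosen only after seeing the data. Calls of named genes were lost in 0 (lot as a random block) to 22 cases (GAPDH covariate) with all arrays kept, in 19 without the lot-1 arrays, and in 228 of 1358 omissions of 1 array, which touched 60 of them. Calls of lists were lost in 17 of 253 such omissions, and 37 of 40 ended with an estimated correlation, which gave the highest adjusted p of the alternatives run for each of the 40. Calls of lists numbered 3 with an estimated correlation and 25 by fry. Counts of changed probe sets moved by over 1.5 times as follows. For E18 against E16 (8) they were 3 with the floor at the 40th percentile, 5 with the stricter filter, 5 with the replicate block, 5 with the lot block and 2 with only both stages in the model. For P0 against E18 (13) they were 56 under quantile normalization, 7 with no filter, 40 with the replicate block, 8 without the lot-1 arrays, and 0 in limma with only both stages, where 769 had an unadjusted p under 0.05. For E16 against E14 (176) they were 63 with only both stages and 272 with the GAPDH covariate, and for P0 against E12 (1705) 430 with only both stages. Array weights, from 0.22 for P0 replicate 4 to 7.82 for E18 replicate 2, gave 3041, 1173, 912, 1153 and 865 for the successive stages, 2911 for P0 against E12, 6462 for the 6 stages and 5298 for the 5 nerve stages. Leaving out each array gave 973 to 1282 for E12 against E9.5, 128 to 217 for E14 against E12, 107 to 181 for E16 against E14, 4 to 11 for E18 against E16, 2 to 715 for P0 against E18, 1063 to 2794 for P0 against E12, 2282 to 3903 for the 6 stages, 867 to 2357 for the 5 nerve stages, and 36 to 45 calls of lists. Settings with only both stages or without an array hold fewer samples, which alone does not give a higher count. E12 against E9.5 had 1844 with only both stages. The median SD of probe sets within a stage was 0.374 at P0 and 0.293 at E16, and 0.176 to 0.22 at the other stages. The model uses 1 spread for all stages, so its standard errors for P0 and E16 can be too small. The cause of the shifts was not tested. No median change over all probe sets moved by more than 0.084 under quantile normalization. Signal near the floor limits the folds given as lower bounds.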

Other observations

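Of 20 measured crest genes 4 rose and 4 fell from E9.5 to E12, or 5 and 4 adjusted over the list alone. Ednrb, the endothelin receptor of crest and glia, rose 11.5-fold from 461 ± 193 to 5050 ± 907 (SD, n = 3 and 3; SE of log2 0.40), while Tfap2b and Pax3 fell. Wnt ligands of the dorsal neural tube were lower at E12, Wnt1 by at least 2.57-fold (SE 0.18) and Wnt3a by at least 2.45-fold (SE 0.12), and Sfrp1, a secreted Wnt inhibitor, rose 8.96-fold (SE 0.36). It fell 6-fold from E12 to P0 (SE 0.36). Of 12 Wnt pathway genes 1 rose and 3 fell to E12, or 2 and 4 adjusted over the list alone, and 1 rose and 3 fell from E12 to P0, or 1 and 4 adjusted over the list alone. Among the Id genes, targets of BMP signalling, Id4 rose 6.10-fold to E12 (SE 0.37) and Id3 2.50-fold (SE 0.20), and Id3 then fell from 2030 ± 209 at E12 to 619 ± 102 at E14 and 140 ± 24.5 at E16. Of 14 BMP/Id genes 4 rose and 1 fell to E12, or 5 and 1 adjusted over the list alone, and 5 fell and 0 rose from E12 to P0, or 5 and 2 adjusted over the list alone. None of these lists was called as a whole (lowest adjusted p 0.15 for the crest, 0.11 for Wnt and 0.28 for BMP/Id).

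Hox genes give position along the trunk. From E9.5 to E12, 4 of 27 fell and 1 rose, or 4 and 3 adjusted over the list alone, with Hoxb5 (2.28-fold, SE 0.21) and Hoxb1 (2.05-fold, SE 0.20) lower and Hoxd8 (2.54-fold, SE 0.25) higher. From E12 to P0, within the nerve, 5 fell and 0 rose, or 6 and 0 adjusted over the list alone. Hoxa5 fell 5.27-fold, from 573 ± 24 to 118 ± 64.3 (SE 0.35, 1 P0 array at the floor), and Hoxb6 at least 4.65-fold, from 395 ± 153 to 69.6 ± 34.3 (SE 0.36). The list was not called in any comparison (lowest adjusted p 0.17), and of all probe sets 14.11% and 16.37% changed over these intervals. In the Notch pathway 1 of 13 genes rose from E12 to P0, Hey1 (2.72-fold, SE 0.24), a target of the pathway, and 2 fell, the same adjusted over the list alone, among them Notch3 (3.37-fold, SE 0.23).

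Other splits of the same arrays into groups of the same sizes were counted for each comparison. For 4 of the 8 counts the share of splits with as many calls was under 0.05. These are single tests with no adjustment over the 8, so they do not exclude chance. For E16 against E14 and for E18 against E16, 1 of 35 splits, the real one, gave as many calls, with 176 against a highest other of 24 and 8 against 4, and for E18 against E16 4 to 11 were called without each array. The others were 1 of 100 drawn splits each over the 6 stages, with 3018 calls against 9, and over the 5 nerve stages, with 1364 against 270. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Real counts and highest others were 1469 and 0 for E12 against E9.5, 218 and 16 for E14 against E12, 13 and 10 for P0 against E18, and 1705 and 0 for P0 against E12. Each real split parts 2 lots. Of the other splits that part as many, the highest counts were 0, 0, 5, 4, 0 and 0 for E12 against E9.5, E14 against E12, E16 against E14, E18 against E16, P0 against E18 and P0 against E12. The others differ in mixing arrays of both stages, which also widens the spread in the model and can lower their counts.

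Along the axis on which arrays of E16 and P0 stand apart, genes of lipid synthesis had the highest percentiles of the 29 lists. Cholesterol synthesis genes had a median r with the axis of 0.69, at percentile 99.2 of matched random lists, and fatty acid and sphingolipid synthesis genes one of 0.75, at percentile 99.6. At the other end stood somite and mesoderm markers (median r -0.60) and epithelial markers (-0.54), both at percentile 0, and endothelial, fibroblast and macrophage markers at percentiles 2.4, 2.7 and 3.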
